A study of Mus musculus with 2 samples.

How the data were processed

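Regulatory innate lymphoid cells (ILCregs), the name the labels give the sorted cells, were taken from the small intestine of 8-week-old IL-10-GFP knockin mice on the C57BL/6 background. These mice carry green fluorescent protein at the locus of the cytokine interleukin 10. Per the labels' protocols and design text, post-sort flow cytometry gave a purity of over 95%, RNA was extracted with TRIZOL and treated with DNase, amplified with an Affymetrix whole-transcript Pico kit, and 5.5 µg of sense-strand cDNA was fragmented, labelled with biotin and hybridised. The series holds 2 arrays of this 1 group, replicate 1 and replicate 2. Nothing in the labels says whether they came from separate mice or sorts, so the spread between them may be technical. No control or comparison population was analysed here, and the gates of the sort are not given in the sources used here.

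The deposited table holds 1 value per feature (transcript cluster) and array. The authors' values, between 2.10 and 19.86, were taken as log2 signal from their range. The log base itself is not stated, so fold limits hold only if it is 2. The submitters' processing notes name MAS5, without a version or a role. Summarization, background correction, scaling and genome build are not given in the sources used here. On the array of replicate 1, 688 features lay above 16, the log2 of the highest 16-bit scanner reading, and 673 did on that of replicate 2; the step that gave such values is not known. The highest value was shared, within 0.001, by 99 features on the array of replicate 1 and by 85 on the other. Such features are called saturated below, and their levels are only lower bounds. Below the highest value, 69 of 2003 features with a mean signal over 12 differed between the arrays by the same amount as the highest values, 0.06, within 0.0001; at 8 other differences looked at, at most 1 feature did. Their difference, and so their SD, is read as set by the ceiling. This was looked at after the data were seen, and members of the gene lists that are such features are named as such. Array medians were 5.02 and 4.90.

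Of 61344 features, 28573 carried 1 gene symbol in the platform annotation, 2014 carried several and 30757 carried none. Only those with 1 symbol were used and named. Symbols were updated through Entrez gene identifiers of the GRCm38.p6 gene table, which held 21166 of the 21456 features with an identifier, and 814 features changed symbol. No coordinates are given because the build of the array annotation is not stated. This gave 28279 genes, 216 of them with several features, for which the feature with the highest mean signal was used.

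Signal that can be read without transcript was gauged from 1678 olfactory, vomeronasal and taste receptor genes, called the reference below. The 95th percentile of these genes was the threshold on each array, 6.74 for replicate 1 and 6.19 for replicate 2, and a gene was called above the threshold only if it was so on both arrays. Of the reference genes themselves, 41 (2.44%) met this. A gene below the threshold was not distinguishable from such signal, which does not show that it is absent.

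With 1 group of 2 arrays no test of a difference between groups was possible, and no p-value is given. Values are means ± SD of log2 signal over both arrays, unless stated otherwise, and the number of arrays limits their precision. For each of 27 gene lists, the median signal was placed among the medians of 10000 random lists of the same size drawn from all named genes. The difference of replicate 2 minus replicate 1 was taken relative to the median difference of all named genes, and a list's median difference was placed among 10000 random lists matched on mean signal in 20 bins. These percentiles describe these arrays; genes are not independent replicates. Probes differ in affinity, so signal does not order transcripts of different genes by abundance. The lists, the threshold and the rule for named genes were fixed before the data were examined. The rule names 26 core genes, the highest, lowest and most different members of each list, the 10 genes of highest signal and the 10 genes most different between the arrays in each direction, and examples were drawn from these. Of the 26 core genes, 18 were measured through a feature with 1 symbol; the others, among them Il2rg, Gata3, Foxp3, Tcf7, Smad2 and Smad4, were not analysed here.

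The list statistics were tested on simulated data over 28279 genes. In 100 simulated lists of 15 genes with a planted difference of 0.5, the mean recovered difference was 0.50 and 93% lay in the upper 2.5% of 1000 random lists. At a planted 0.25, 37% did, and with none planted 3% did and 0% lay in the lower 2.5%. The simulated differences were independent normal noise with the same SD for every gene. Real genes of a list can vary together, so these rates need not hold for the real lists. For level, a planted shift of 2 on the log2 scale put 82% of such lists above the 95th percentile and no shift put 6% there. Alternatives tried were quantile normalization, the median over a gene's features, the 90th and 99th percentiles of the reference, a reference of 57 keratin-associated protein and Rhox genes, lists limited to genes above the threshold, no centring, 5 bins and each array alone. Random lists of protein-coding genes, lists without saturated features, and list differences without features at or set by the ceiling, were added after seeing the data. A pseudocount was not needed on log2 values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.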

Results

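Gene expression was profiled on whole-transcript arrays in ILCregs sorted from the small intestine of IL-10-GFP knockin mice, with 2 arrays of this 1 group. The design holds no other cell population, so the comparisons it allows are those of named genes and gene groups with the reference on the same arrays, and of the arrays with each other. In all, 8972 of 28279 named genes (31.7%) lay above the reference threshold on both arrays, among them 6326 of 16218 protein-coding genes outside the reference (39.0%). Across genes the arrays correlated with a Pearson's r of 0.986 and a Spearman's rho of 0.969. These describe agreement over genes, which are not independent replicates. The replicate SD was 0.31 on the log2 scale over all named genes and 0.34 over those above the threshold.

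The gene at whose locus these mice carry green fluorescent protein, Il10, was among the genes above the threshold. Il10, which encodes interleukin 10, had a signal of 10.82 ± 0.32 (SD, n = 2), which lay 4.35 on the log2 scale above the mean threshold. Ptprc, the pan-leukocyte antigen CD45, reached 12.21 ± 0.10 and Il7r, the interleukin 7 receptor of innate lymphoid cells, 8.92 ± 0.56. Of 18 core genes measured, 15 lay above the threshold on both arrays. The inhibitor of DNA binding Id2 had a signal of 12.08 ± 0.21 and its relative Id3 a signal of 9.75 ± 0.42, and the transcription factor gene Sox4 had 9.42 ± 0.13. Tgfb1, encoding transforming growth factor beta 1, stood at 9.16 ± 0.22, and its receptor genes Tgfbr1 and Tgfbr2 at 8.95 ± 0.55 and 11.83 ± 0.36. Il2rb, the beta chain shared by the receptors for interleukins 2 and 15, stood at 9.95 ± 0.16, Rora at 8.20 ± 0.41 and Smad3 at 7.61 ± 0.16. Tbx21, which encodes the type 1 lymphocyte regulator T-bet, gave 6.15 ± 0.08 and Thy1, a surface marker of T cells and many innate lymphoid cells, 5.64 ± 0.11. Neither exceeded the threshold on either array. Il2ra exceeded it only on the array of replicate 2, with 7.18 against 6.71 on the other. The lineage markers Cd3e (9.79 ± 0.16), Cd4 (7.95 ± 0.62) and the epithelial adhesion molecule gene Epcam (11.97 ± 0.16) also lay above the threshold on both arrays. With the stricter 99th percentile of the reference, Smad3 and Cd4 no longer did. As markers of other lineages passed, the arrays do not show which cells gave the signal of Il10 or the other core genes.

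**Figure D1:**
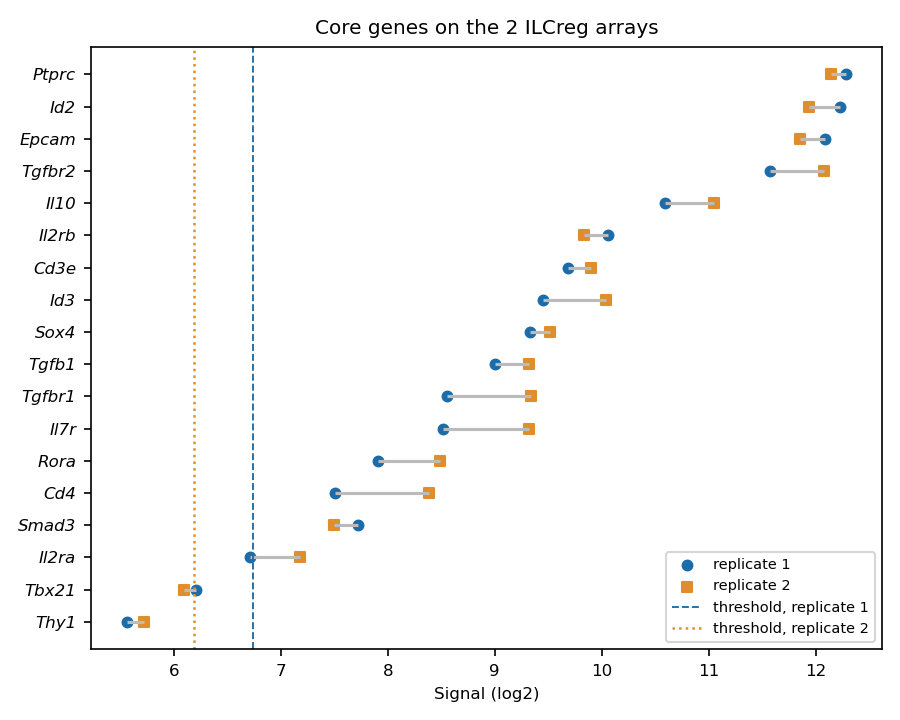
Signal (log2, horizontal axis) of the 18 measured core genes on the array of replicate 1 (circles) and replicate 2 (squares), with each array's reference threshold (6.74 and 6.19, vertical lines). Il10, Id2, Id3, Sox4 and the TGF-beta receptor genes lie to the right of both thresholds, Tbx21 and Thy1 to the left of their own array's, and Il2ra passes only on the array of replicate 2.

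Immunoregulatory genes and TGF-beta signalling genes were above the threshold in most cases on these arrays. In the list of immunoregulatory cytokines and receptors 13 of 17 measured members passed, with Tgfb3 (11.57 ± 0.11) and the inhibitory receptor gene Ctla4 (10.92 ± 0.10) highest, and with the cytokine subunit gene Ebi3 (4.09 ± 0.02) and Il12a (4.15 ± 0.27) lowest. Of 14 measured TGF-beta receptor and SMAD genes 11 passed, with the co-receptor gene Tgfbr3 at 11.64 ± 0.19, while the inhibitory Smad6 stood at 5.56 ± 0.10. The median signals of these lists, 7.71 and 8.85, lay at percentiles 99.65 and 99.98 of random gene lists of the same size. Among only genes above the threshold, in lists and random lists alike, they lay at 38.5 and 82.5, no longer past the 95th percentile. Of 18 genes of common gamma chain cytokine signalling 14 passed, led by Il4ra (13.75 ± 0.04) and the kinase gene Jak1 (11.98 ± 0.25), while the feedback inhibitor gene Socs3 was at 4.23 ± 0.06. Among factors linked to Il10 transcription, 11 of 13 passed. The medians of these lists, 8.50 and 8.83, lay at percentiles 99.97 and 99.85, and at 81.4 and 69.7 among genes above the threshold. Stat3 and Fosl2 were highest at 11.91 ± 0.33 and 11.84 ± 0.22, and Nfil3 was lowest at 5.97 ± 0.15. Although the sort was stated to be over 95% pure, marker lists of stroma, epithelium and macrophages had median signals of 12.08, 11.37 and 9.86 on the same arrays, and the plasma cell gene Jchain 17.79 ± 0.45. The arrays do not show which cells a transcript came from. The signals of genes that other cells also express, such as Tgfb3, Tgfbr3 and Il4ra, may thus not come from the ILCregs. This limit holds for Il10, Ctla4 and Tgfb1 too, since T cell and macrophage markers such as Cd3e (9.79 ± 0.16) and C1qb (12.37 ± 0.25) also passed.

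Transcription factor, surface and homing genes were divided between those above and those at reference level. Of 21 transcription factors of innate lymphoid cells and lymphocytes, 12 passed on both arrays, 2 on 1 array and 7 on neither. Id2 and Id3 were highest, while Lef1 (3.78 ± 0.05), Tox2 and the natural killer cell factor gene Eomes (5.18 ± 0.51) were not above the threshold. Of 17 surface and gate genes 9 passed, with the adhesion receptor gene Cd44 at 11.28 ± 0.02. The natural cytotoxicity receptor gene Ncr1 (4.67 ± 0.06) and Klrk1 (5.38 ± 0.05) were lowest. Of 19 genes of gut homing and tissue residency 10 passed, including the G-protein regulator gene Rgs1 (12.96 ± 0.21) and the integrin gene Itgb1 (12.17 ± 0.09), while the chemokine receptor gene Ccr4 stood at 4.08 ± 0.07. These 3 lists lay above the 95th percentile of random lists of all named genes (97.8, 98.2 and 98.8), but not of random lists of protein-coding genes (91.9, 93.8 and 94.98) or of lists among genes above the threshold (58.1, 93.4 and 89.0).

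Genes of stress, respiration and innate sensing had high signals. Of 19 measured immediate early and dissociation stress genes 17 passed, with Fosb at 17.36 ± 0.22, the phosphatase gene Dusp1 at 15.52 ± 0.51, the orphan receptor gene Nr4a1 at 14.53 ± 0.52 and Jun at 13.54 ± 0.61. All 17 oxidative phosphorylation genes, all 14 cytosolic ribosomal protein genes (Rplp0 with a difference between the arrays set by the ceiling) and 15 of 16 interferon-stimulated genes passed, the exception being Mx1 (5.83 ± 0.08). Of 17 genes of Toll-like receptor and NF-kB signalling 13 passed, with Il1b at 14.88 ± 0.26 and Rel at 14.45 ± 0.33, against 4.78 ± 0.03 for the flagellin receptor gene Tlr5. Il1b, which macrophages also express, may likewise not come from the ILCregs, and the cell of origin is open for the other genes of these lists too. In the cell cycle list 16 of 23 passed. The proliferation marker Mki67 and the replication clamp gene Pcna were highest at 11.73 ± 0.96 and 12.74 ± 0.30, whereas the mitotic genes Cenpf (5.56 ± 0.01) and Bub1 (5.70 ± 0.01) were at reference level. The medians of these 6 lists lay at or above percentile 99.73 of random lists of all named genes and 99.03 of random protein-coding lists. Among genes above the threshold, only the stress and oxidative phosphorylation lists stayed past the 95th percentile, and the cell cycle (25.8), interferon (73.2), ribosomal protein (88.8) and Toll-like receptor (92.8) lists did not.

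Markers of the innate lymphoid subsets ILC2 and ILC3 were mostly at reference level, and those of ILC1 and natural killer (NK) cells were divided. In the ILC3 list 3 of 11 measured members passed, with Il1r1 at 9.63 ± 0.16, and the cytokine genes Il17a (3.99 ± 0.02), Il17f (4.13 ± 0.10) and Il22 (4.33 ± 0.67) did not. In the ILC2 list 2 of 8 passed, the prostaglandin synthase gene Hpgds (9.07 ± 0.28) and Lpcat2 (7.71 ± 0.35), and Il4 and Arg1 stood at 4.42 ± 0.20 and 5.04 ± 0.33. Of 14 ILC1 and NK cell genes 5 passed on both arrays, 2 on 1 array and 7 on neither. Among the 5 were the granzyme genes Gzmb (13.39 ± 0.02) and Gzma (11.55 ± 0.16), and Ncr1 and Klre1 were the lowest of the list. The median signals of the ILC3, ILC2 and ILC1 and NK cell lists fell at percentiles 10.6, 54.4 and 81.5 of random lists of all named genes. Among random protein-coding lists they fell at 3.6, 31.2 and 57.8. The 12 measured T cell genes were split, with Cd3e, Cd3g (9.11 ± 0.20) and 4 others passing and Cd247 (5.13 ± 0.27) and Cd8a (5.33) not. Of 9 regulatory T cell genes 5 passed, including Tnfrsf4 at 10.23 ± 0.43, and Gpr83 was at 3.92 ± 0.03. The medians of the T cell and regulatory T cell lists lay at percentiles 94.4 and 93.2 of random lists of all named genes. Among random protein-coding lists they lay at 85.5 and 86.2.

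Of the remaining cell type lists, those of epithelium, stroma and macrophages had the highest medians, and the others were lower. Of 20 intestinal epithelial genes 17 passed, with the keratin gene Krt8 at 15.59 ± 0.24, the goblet cell gene Agr2 at 13.83 ± 0.29 and the fatty acid binding protein gene Fabp1 at 12.47 ± 0.81, and with the stem cell marker Lgr5 (5.07 ± 0.37) and the endocrine marker Chga (5.32 ± 0.28) at reference level. Of 13 stromal and smooth muscle genes 12 passed. The matrix genes Dpt and Dcn had mean signals of 19.83 and 19.31. Dpt was saturated on both arrays, and Dcn differed between them by the difference of the highest values, so neither SD measures the spread between samples. Of 13 macrophage and monocyte genes 12 passed, with the lysozyme genes Lyz2 at 14.71 ± 0.07 and Lyz1 at 13.57 ± 0.28, which are near-identical copies whose probes may share signal. The scavenger receptor gene Cd163 was at 5.58 ± 0.09. The medians of these 3 lists, 11.37, 12.08 and 9.86, lay at or above percentile 99.96 of random lists of all named genes and at or above percentile 99.99 of random protein-coding lists. Of 14 B and plasma cell genes 8 passed, led by the antibody joining chain gene Jchain (17.79 ± 0.45) and the secretory regulator gene Xbp1 (13.50 ± 0.37), whereas the B cell genes Pax5 (4.86 on both arrays) and Fcer2a (4.65 ± 0.11) did not. The median of this list lay at percentile 96.7 of random lists of all named genes and 90.2 of protein-coding ones, and at 10.6 among genes above the threshold. In the dendritic cell list 5 of 11 passed, with the MHC class II gene H2-Aa at 14.15 ± 0.19 and Xcr1 at 4.39 ± 0.08. Of 12 endothelial genes 4 passed, Eng being highest at 8.38 ± 0.48. Granulocyte and mast cell genes (3 of 18, Prg2 highest at 8.56 ± 0.54), erythrocyte and platelet genes (1 of 6, Pf4 at 11.44 ± 0.16) and enteric neuron and glia genes (1 of 10, Vip at 8.11 ± 0.30) were mostly at reference level.

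**Figure D2:**
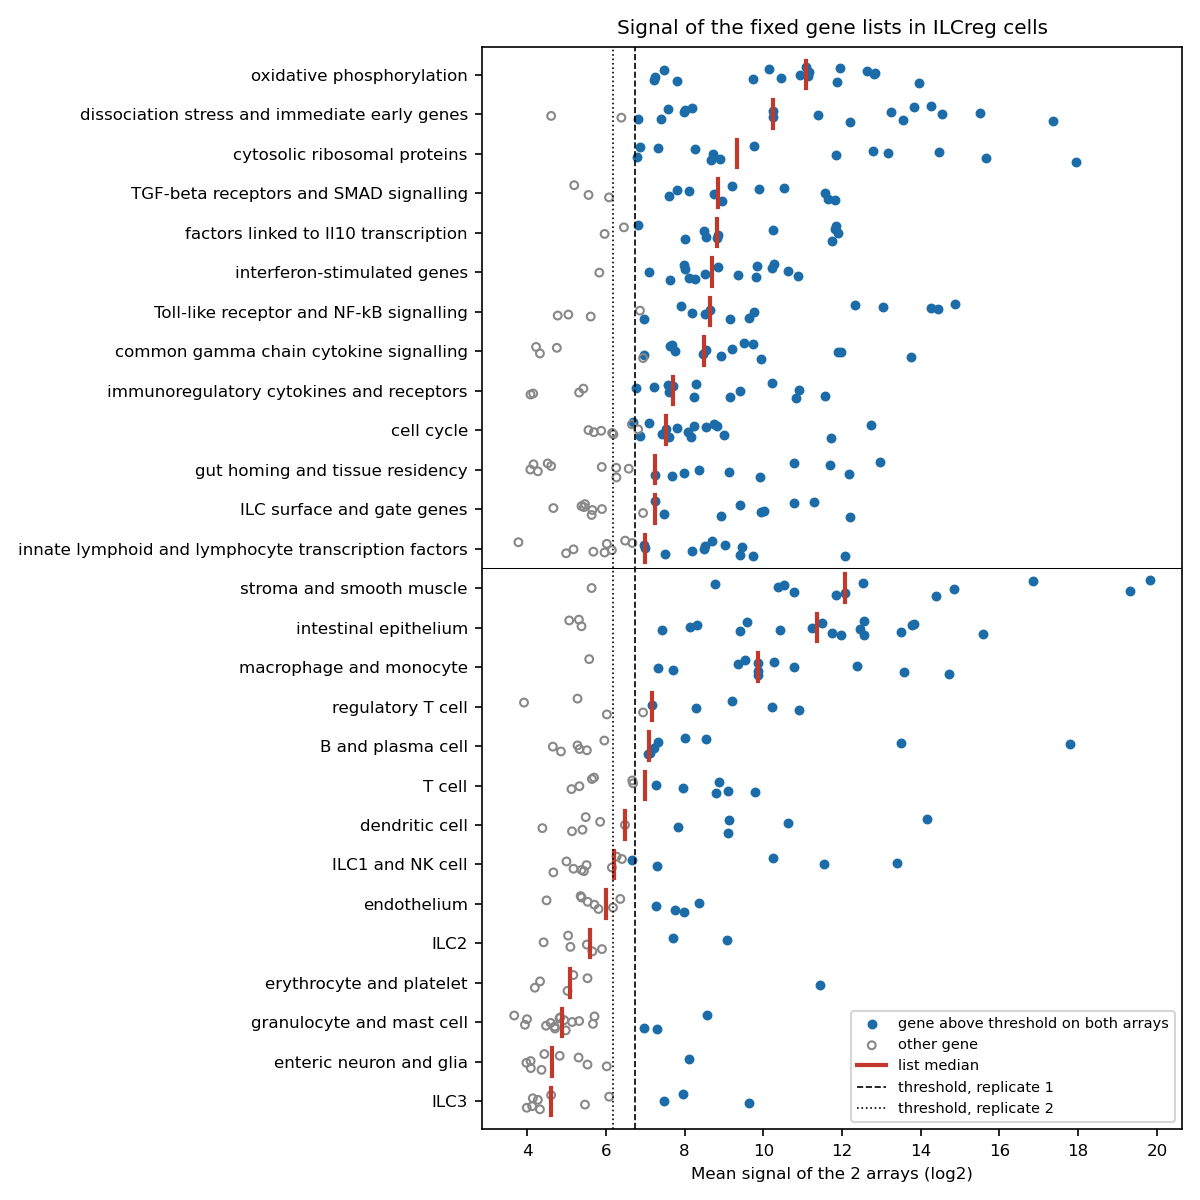
Mean signal of both arrays (log2, horizontal axis) for each measured gene of the 27 lists, with gene groups in the upper block and cell type markers in the lower. Filled points passed the threshold on both arrays, open points did not, vertical bars are list medians and the vertical lines are the thresholds of each array (6.74 and 6.19); among cell types, the medians of stroma (12.08), epithelium (11.37) and macrophages (9.86) lie farthest to the right and that of ILC3 (4.61) to the left of both thresholds.

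The highest signals were saturated. The 10 genes named as highest, Dpt, the heat shock cognate Hspa8, the immunoglobulin segments Ighv1-2, Ighv9-3 and Igkv19-93, the microRNA genes Mir1954, Mir3470b and Mir3473a, the gene model Gm10925 and the small nuclear RNA gene Rn7sk, belonged to 14 named genes at the highest value of both arrays, 19.80 and 19.86, and have no order among them. Immunoglobulin segments and repeat-derived RNAs can share probe signal with near-identical copies.

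The arrays differed by more than 2-fold, relative to the median gene, for 373 of the 8972 genes above the threshold, 196 of them higher on the array of replicate 2 and 177 on that of replicate 1. Among the largest differences toward replicate 2 were the fibrillar collagen genes Col3a1 (11.06 on the array of replicate 1 against 13.10, a centred difference of 2.08) and Col1a2 (10.94 against 12.78, 1.89), together with the ubiquitin ligase adaptor gene Wsb1 (2.27), the solute carrier gene Slc35f2 (2.16) and Bcap31 (2.07). The T cell receptor segment Traj47 and the genes Ggps1, Prps1, Scfd1 and Gem completed the 10, with centred differences from 1.76 to 2.01. Col1a1, named after its values were seen, differed by 1.74. Toward replicate 1 the largest were Pcp4 (-2.64), the immunoglobulin segment Igkj3 (-2.44) and 3 heavy chain variable segments (from -2.34 to -1.89), the T cell receptor segment Traj38 (-2.16), and Ufm1, Izumo4, the Paneth cell defensin gene Defa27 and Lyrm4, from -1.76 to -1.60. Each rests on 1 array against 1 and has no replicate check.

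By list, the median differences of 4 of 27 lists lay in the upper 2.5% of matched random lists, toward replicate 2, and 0 in the lower 2.5%. Chance would give 1.35 lists outside these bounds if the lists behaved as random lists of all named genes. The lists share some genes, so they are not independent. Among protein-coding genes above the threshold, 145 were over 2-fold higher on the array of replicate 2 and 59 on the other. Lists of protein-coding genes may therefore lean toward replicate 2 more often than that rate. Random lists of protein-coding genes alone were not run for the differences, so this was not tested. Factors linked to Il10 transcription had a median centred difference of 0.36, with 11 of 13 higher on the array of replicate 2 and Hif1a at 0.66 and Batf at -0.82. Immunoregulatory genes had a median of 0.31 with 12 of 17 higher, Tigit by 1.23 and Nt5e by 0.88. B and plasma cell genes had a median of 0.23 with 11 of 14 higher, Jchain by 0.69. The most different members, Cr2 at -1.42 and Tnfrsf17 at -0.79, went the other way and were not above the threshold. Among genes above the threshold the median of the B and plasma cell list was 0.48. Of 174 immunoglobulin variable segments above the threshold, which are not in that list, 14 were over 2-fold higher on the array of replicate 1 and 1 on that of replicate 2. The median of gut homing genes was 0.21, with Cxcr4 at 1.09 and Itga4 at 0.88. The calls of 3 lists depended on the setting. The immunoregulatory list missed the bound after quantile normalization (percentile 97.3), where its median fell to 0.20. The homing list missed it there too (97.2, median 0.18), with 5 bins (96.9) and among genes above the threshold (93.3, median 0.30). The B and plasma cell list missed it with 5 bins (97.3). The number of bins changes only the random lists, so the medians stayed the same there. The stromal list had a median of 0.21 at percentile 92.6 over its 13 genes. Without Dpt and Dcn, whose differences were set by the ceiling, the other 11 were all higher on the array of replicate 2, with a median of 0.44 at percentile 99.4, past the bound; this was computed after the data were seen. In the epithelial list 13 of 20 were higher on that of replicate 1, with a median of -0.15 at percentile 5.41. Il10 itself had a centred difference of 0.51.

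**Figure D3:**
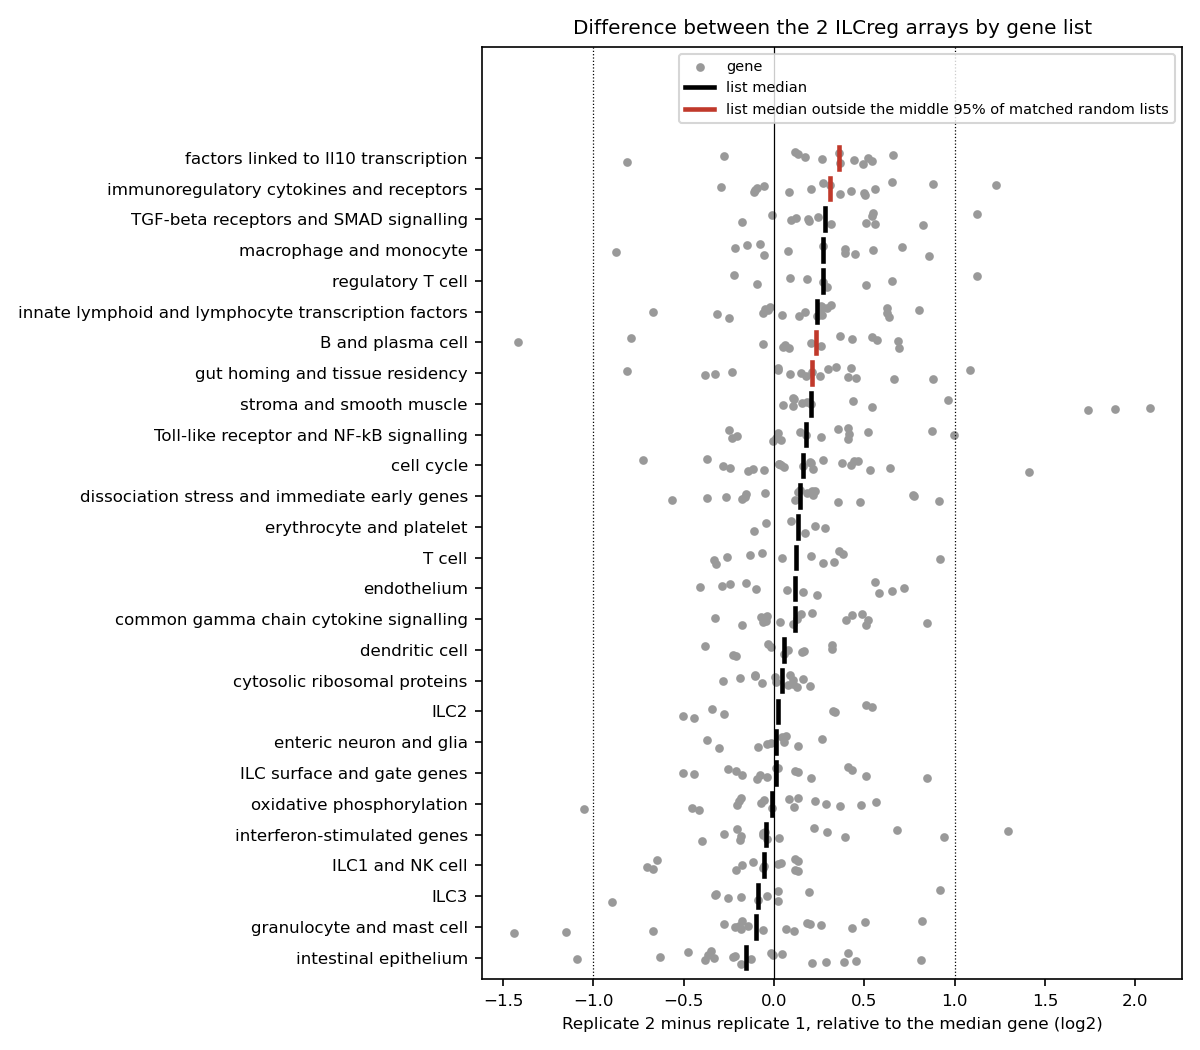
Difference of replicate 2 minus replicate 1 relative to the median gene (log2, horizontal axis) for each gene (grey points) and each list's median (bars); dotted lines mark 2-fold. The 4 red bars are list medians in the upper 2.5% of matched random lists, between 0.21 and 0.36, and the 3 points beyond 1 in the stromal list are Col1a1, Col1a2 and Col3a1.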

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

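This count was taken only after the data were seen. Among the 30757 features without a gene symbol, which entered none of the results, 4507 (14.7%) lay above the reference threshold on both arrays. This drew attention because it is signal in data left unused. No gene is named for them here.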

How the results depend on the processing

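Random lists of protein-coding genes, lists without saturated features and list differences without features at or set by the ceiling were tests chosen only after the data were seen. The count of genes above the threshold stayed within 1.5 times its value of 8972 under the 90th percentile of the reference (11026), the keratin-associated protein and Rhox reference (9843) and the median over features (8941), and fell to 5588 at the 99th percentile, which is stricter by construction. Without replicate 1 or replicate 2 it was 9148 to 10925. Quantile normalization keeps ranks, so its identical count says nothing. Genes over 2-fold apart numbered 373, 976 over all named genes and 229 above the 99th percentile, since more or fewer genes enter, and 369 to 469 otherwise. The balance between the arrays depended on the genes counted. Over all named genes 418 were higher on the array of replicate 2 and 558 on that of replicate 1. Among protein-coding genes above the threshold these counts were 145 and 59. The SD of the difference moved from 0.44 to between 0.43 and 0.47. Lists above the 95th percentile of random lists numbered 17, between 13 and 17 under the other alternatives, and 5 when lists and random lists held only genes above the threshold: epithelium, stroma, macrophages, oxidative phosphorylation and stress genes. Without replicate 2 the B and plasma cell list missed, at percentile 94.85 (16 lists against 17 without replicate 1). Lists that differed between the arrays numbered 3 to 5 in every alternative, but only 2 of the 4 were called after quantile normalization and with 5 bins, and 3 when limited to genes above the threshold. Other lists entered: TGF-beta genes after quantile normalization, stroma among genes above the threshold and without features set by the ceiling (there beside all 4 others), and lymphoid transcription factors and, toward replicate 1, epithelium with 5 bins. In the 4 called lists the median kept its sign throughout; the cause of the lost calls was not tested. Of 18 core genes, 15 passed in the main setting. Tbx21 and Il2ra also passed at the 90th percentile, and Il2ra with the other reference. No paired analysis was possible because there is only 1 group. The pseudocount alternative was not run because values are already on a log scale. Below the threshold, signal over background limits what can be read.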

Other observations

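The gene lists and gene kinds below were chosen after the signals of the arrays had been seen, and the tests of the secreted products and of the gene names were chosen only after their result was seen. Digestive gland genes stood out. Tff2, a trefoil peptide of gastric and duodenal glands, was saturated on the array of replicate 1, so that its mean of 19.79 is a lower bound, and the gastrokine gene Gkn3 had a signal of 16.30 ± 0.24 and the gland mucin gene Muc6 14.34 ± 0.83. Of 10 measured gastric and duodenal gland genes 7 passed the threshold, whereas Atp4a and Atp4b, the parietal cell proton pump, were at 4.48 ± 0.19 and 4.20 ± 0.02. The pancreatic enzyme genes Ctrb1 (19.65, with a difference between the arrays set by the ceiling), Amy2b (18.82 ± 0.09), Cpa1 (17.76 ± 0.06), Cel (15.23 ± 0.06) and Cela2a (15.62 ± 0.10) were all above it, as were all 15 acinar genes first looked at, while 0 of 12 islet genes passed, with Ins2 at 5.29 ± 0.02 and Gcg at 5.20 ± 0.03.

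Antibody segments were also high. Of 199 named immunoglobulin variable segments 174 (87.4%) passed, and the median of all 199 was 11.93. Of the 174, 14 were over 2-fold higher on the array of replicate 1 and 1 on the other. Of 133 T cell receptor joining and variable segments 15 (11.3%) passed, with a median of 5.31. Only the T cell receptor set holds joining segments, so these shares do not compare like with like. Segments of a family can share probe signal. Small nucleolar RNA genes were the least alike between the arrays among the 5 kinds of gene compared. Of 30 that passed, 40.0% differed by more than 2-fold, 10 of them higher on the array of replicate 1 and 2 on the other, against 3.22% of 6326 protein-coding genes.

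For these digestive gland transcripts in a sort of over 95% purity, raised signal for abundant transcripts of any tissue is argued against, since 0 of 16 hepatocyte and 0 of 15 skeletal muscle genes passed and the higher of these lists, muscle, lay at percentiles 0.39 and 1.06 of random protein-coding lists. Wrong gene names throughout the table are argued against too, since the chemosensory receptor genes lay at percentile 0 of 1000 random lists on both arrays. That test was chosen after its result was seen. It cannot exclude wrong names for a few genes, such as the digestive gland genes themselves. For the pancreatic genes, cross-hybridisation within gene families is argued against only for acinar genes taken to have no close family member. Those genes, with Sycn at 14.18 ± 0.03 and Pla2g1b at 10.34 ± 0.55, lay at percentile 99.99 on the lower array. Of these 9 genes 7 passed the threshold, and the same 7 are those that passed in the acinar lists below, so the tests are not independent. Their signal does not show how much cross-hybridisation adds to enzyme genes with relatives, such as Ctrb1 and Amy2b, and for these it stays open. The gastric and duodenal gland genes were not covered, so for them cross-hybridisation was not tested. RNA of pancreatic acinar cells was predicted to put the median of 14 acinar genes not looked at before in the upper 2.5% of random lists. This median lay at percentile 67.54 on the lower array, so the prediction was missed. Of the 14 genes 7 did not pass the threshold, among them the transcription factor genes Ptf1a, Rbpjl, Bhlha15 and Nr5a2 at 3.53 to 6.11. The miss was not confined to these, since the secreted products Dnase1 (4.75 ± 0.15) and Ctrc (6.37 ± 0.03, above on 1 array only) did not pass either. A median over that many genes near the floor cannot decide the question. The bound was thus badly chosen, as was seen only after the result, and acinar cells stay open. The 9 secreted products among them lay at percentile 99.99, but they were split off after their values were seen and hold the 7 genes that passed, so this decides nothing; RNA of secreted acinar products in the samples, which a sort of lymphoid cells is meant to exclude, stays open too, with Zg16 and Gp2 also known from gut epithelium and transcription in the sorted cells themselves untested.

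Col1a1, Col1a2 and Col3a1 were higher on the array of replicate 2 by at least 1.74 (log2, centred). More stromal RNA alone would move other stromal genes about as much. However, 22 such genes not looked at before had a median difference of 0.25, with 19 higher on that array and 0 by over 2-fold. The 95% bootstrap interval of this median, 0.12 to 0.41, was taken over the genes of 1 pair of arrays. It does not measure the spread between samples, and genes that vary together can make it too narrow. Scaling between the arrays is argued against as well, since the smallest of the 3 differences was 1.80 after quantile normalization. A small shift in stromal content, and a change specific to these collagens between samples or in their preparation, stay open and were not tested, as there is 1 array on each side.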
